A study of Mus musculus with 2 samples.

How the data were processed

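Single-cell RNA-seq libraries were prepared from the aorta of Apoe-/- mice of 12 weeks with an abdominal aortic aneurysm induced by angiotensin II. Per the labels, the tissue was dissected into 5 segments and digested with enzymes, and 5000 cells were targeted per library with 10x Chromium 3' v3 chemistry. There are 2 libraries, 1 per group; the title initials were read as DMSO and inhibitor, and the name, dose and timing of the inhibitor, the number of animals per library and the segment of each cell are not given in the sources used here. The values deposited by the authors are raw UMI counts per gene and cell barcode, made with Cell Ranger 6.1.1 per the file headers and with GRCm38 per the submitters' processing notes. Seurat is also named in the submitters' processing notes, with no step given. Every barcode in the deposited counts holds at least 500 UMIs; how barcodes were chosen is not given in the sources used here. All 55450 gene rows match GENCODE M21, which was used for gene types and coordinates.

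Cells were kept with at least 200 genes and at most 20% mitochondrial UMIs. This removed 18 DMSO and 10 inhibitor barcodes for few genes, and 449 (4.92%) and 283 (3.47%) for mitochondrial UMIs. Doublets were called with Scrublet per library at an expected rate of 6%. Its automatic threshold failed in the DMSO library (0.665, with 0 cells called), so the threshold of the inhibitor library (0.218) was used for both after this was seen; 209 DMSO cells (2.29%) and 423 inhibitor cells (5.19%) were removed. Both libraries were clustered together, without integration, on 2000 variable genes from which all listed genes and cell type markers were left out, after scaling each cell to 10000 UMIs, with 30 principal components, 15 neighbours and Leiden resolution 1 (seed 0).

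The 35 clusters were named from marker lists. A marker counted where at least 20% of the cluster's cells held it and its log2 level was at least 1 above percentile 25 of the other clusters. A name needed at least 3 markers, a score of at least 1.5, a median of at least 1000 UMIs and 10 leading genes that did not speak against it. This is the fourth version of the rule: 3 earlier versions were replaced after the clusters had been seen, and all 3 were run as alternatives. It named 30 clusters in 13 classes and left 5 unnamed; the 5 classes with at least 100 cells in each library were compared. Names carry "-like" because they rest on markers alone. Clusters differ in the level of their leading genes, so the class values of these genes follow the cluster makeup. This also holds for listed genes and markers, which were left out of the clustering. Values within clusters are given for some of the lists and genes.

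Counts were summed per class and library and scaled to CPM, and the ratio of inhibitor to DMSO was given an exact 95% interval from the counts. With 1 library per group no test was run. A gene was higher or lower where the ratio was at least 1.5-fold and the interval left out 1. Log2 ratios were computed after adding 5 CPM. List members were measured with at least 20 CPM in 1 library, at least 20 UMIs over both and at least 20% of the CPM of the class where the gene was highest, to limit the effect of free RNA. Each list median has an order-statistic interval and its percentile among 10000 random lists of equal size matched on expression, as a description of these libraries. Shares have exact Clopper-Pearson intervals, and a count of 0 is read as up to 3 cells. The interval of a log2 share ratio was formed from the opposite ends of the 2 share intervals. It is therefore wider than a 95% interval of the ratio, and holding 0 is no sign of equal shares.

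Named genes were picked by a rule set before the data were examined: with at least 50 CPM in 1 library and 30 UMIs over both, the 10 highest and 10 lowest ratios in the 3 largest classes and 5 of each in the others, plus up to 4 members per list and direction, and Malat1 and Apoe always. The rule named 213 genes in 296 gene and class pairs. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and T cell receptor genes were left out of the ranking. Malat1 was picked from general knowledge of the study, and no label used here names it. The filters, clustering settings, gene lists and 17 alternatives were also set before the data were examined, and 5 alternatives were added later.

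The gene ratios and list percentiles were tested on simulated counts, drawn for both libraries from a pooled profile of each class. Such counts hold no variation between libraries and no difference in cluster makeup or free RNA, so they test counting error only. Filtering, clustering and naming were not tested in this way. Of genes simulated with a 2-fold difference, 92.9% were called in Schwann-like cells, the lowest of the 5 classes; of genes simulated without one, at most 2.27% were called. Analyses used Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.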

Results

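Single-cell RNA-seq profiles were collected from aortic tissue of Apoe-/- mice, 12 weeks old, with an abdominal aortic aneurysm induced by angiotensin II. Apoe-/- mice lack apolipoprotein E and carry high plasma cholesterol, and angiotensin II is a peptide hormone that raises blood pressure. The design sets tissue given DMSO, a solvent, beside tissue given an inhibitor that the labels do not name. The titles shorten the groups to initials, which were read as DMSO and inhibitor from the series design. Each group holds 1 library, so there are no replicates, no tests and no p-values. Intervals of shares and of single genes cover counting error only. Intervals of list medians cover the spread among the list's members. No interval covers variation between libraries. The DMSO library held 9125 barcodes and 101139161 unique molecular identifiers (UMIs, each standing for 1 captured transcript). The inhibitor library held 8149 barcodes and 79648307 UMIs. The target was 5000 cells each. After filtering, 8459 cells with a median of 7935 UMIs and 2839 genes remained in the DMSO library, and 7445 cells with a median of 8977 UMIs and 2923 genes in the inhibitor library.

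The first comparison asked which cell types made up the aneurysm tissue of each library. Smooth muscle-like cells, the contractile cells of the aortic media, were 41.7% of the inhibitor library (3104 cells; exact 95% Clopper-Pearson interval 40.6 to 42.8%) and 9.03% of the DMSO library (764 cells; 8.43 to 9.66%), a 4.62-fold higher share. Macrophage-like cells, which take up debris and lipid in the wall, were 8.45% of the inhibitor library (629 cells; 7.83 to 9.10%) and 18.8% of the DMSO library (1591 cells; 18.0 to 19.7%). Adipocyte-like cells, the fat-storing cells of perivascular tissue, were 82 cells of the inhibitor library (0.877 to 1.37%) and 10.2% of the DMSO library (859 cells; 9.52 to 10.8%), so that their share was 9.22-fold higher in the DMSO library. Fibroblast-like cells, the matrix-producing cells of the adventitia, had similar shares of 26.5% in the inhibitor and 23.8% in the DMSO library.

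T cell-like, neutrophil-like, endothelial-like and Schwann-like cells were smaller parts of the inhibitor library. T cell-like cells were 0.900% of it (67 cells; 0.698 to 1.14%) against 2.85% of the DMSO library (241 cells; 2.50 to 3.23%), and neutrophil-like cells were 0.685% (51 cells; 0.510 to 0.900%) against 2.80% (237 cells; 2.46 to 3.18%). Endothelial-like cells, which line the vessels, were 6.77% against 9.10%, with a log2 share ratio of -0.43 (interval -0.65 to -0.21). Their clusters 8 and 19 were smaller parts of the inhibitor library, but cluster 12 was 3.33% against 2.32%. Schwann-like cells, the glia of peripheral nerves, were 3.05% against 5.49%, with a log2 share ratio of -0.85 (-1.17 to -0.53). Their clusters 16 and 20 were smaller parts, but cluster 23 was 0.954% against 0.780%. Lymphatic endothelial-like cells (88 and 137; log2 share ratio -0.45, interval -1.01 to 0.10), dendritic-like cells (36 and 82) and pericyte-like cells (8 and 38 in the inhibitor and DMSO library) were rarer. B cell-like cells were 1 cell in the inhibitor library and 32 in the DMSO library, a log2 share ratio of -4.82 (-10.62 to -1.79). Mesothelial-like cells were 33 cells of the DMSO library and 0 of 7445 in the inhibitor library, which allows a share of up to 0.0403%. Cells left unnamed were 9.05% of the inhibitor and 14.1% of the DMSO library. Among them, 4 clusters with medians under 1000 UMIs, a minimum set after the clusters had been seen, held 6.55% and 10.0%. A further unnamed cluster, led by the antigen presentation genes H2-Eb1, H2-Aa and Cd74 and the dendritic marker Cd209a, held 2.50% and 4.09%. Shares of 1 library sum to a fixed total, so a gain in 1 class lowers all others. Among smooth muscle-like and fibroblast-like cells alone, the smooth muscle-like share was 61.1% (59.8 to 62.5%) in the inhibitor and 27.5% (25.8 to 29.2%) in the DMSO library. The log2 share ratio of fibroblast-like cells, 0.15 (0.04 to 0.26), turned to -0.0054 when only cells with at least 1000 genes were used.

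**Figure D1:**
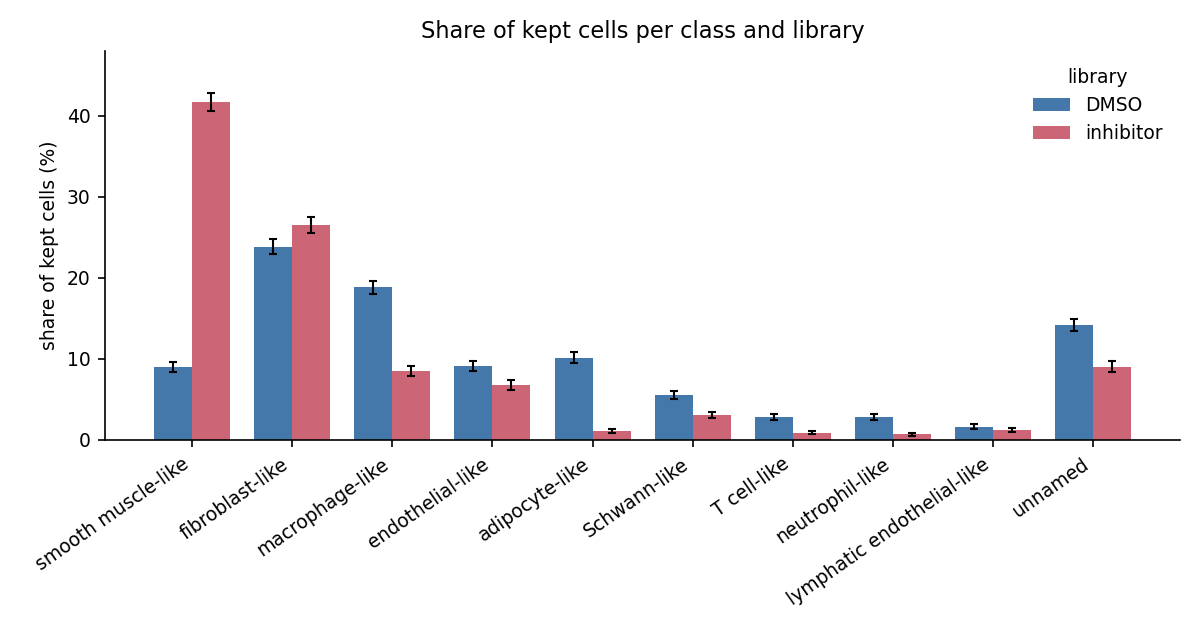
Share of kept cells (percent, vertical axis) for the larger classes and for unnamed cells in the DMSO and the inhibitor library (bars), with exact 95% binomial intervals that cover counting error only. Smooth muscle-like cells stand at 9.03% and 41.7%, macrophage-like cells at 18.8% and 8.45%.

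The next comparisons asked how expression within each class differed between the libraries, from UMIs summed per class and library and scaled to counts per 1000000 UMIs (CPM). A gene was counted as higher or lower where its CPM ratio was at least 1.5-fold either way and its 95% counting interval left out 1. Each gene list is given with the median log2 ratio of its measured members, inhibitor over DMSO.

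In smooth muscle-like cells the heat shock genes stood highest in the inhibitor library. Hspb1, a small heat shock protein abundant in muscle, reached 12492 CPM against 2141 CPM in the DMSO library, a ratio of 5.83 (95% counting interval 5.76 to 5.91). Hspa1b and Hspa1a, which encode the stress-inducible HSP70 chaperone, were at 1600 against 195 CPM (8.20; 7.87 to 8.55) and 3069 against 422 CPM (7.28; 7.08 to 7.49). The HSP110 co-chaperone gene Hsph1 was at 1083 against 214 CPM and the cytosolic HSP90 gene Hsp90aa1 at 3137 against 748 CPM. The HSP40 co-chaperone gene Dnajb1 was at 276 against 65.2 CPM, and the mitochondrial chaperonin gene Hspd1 at 581 against 142 CPM. Of 18 measured members of the heat shock and unfolded protein list, 12 were higher and 0 lower, with a median log2 ratio of 1.85 (interval 0.41 to 2.06) at percentile 100 of 10000 random lists matched on expression. The 6 members between the limits were Calr, Pdia4 and Hsp90b1, chaperones of the endoplasmic reticulum, and the stress transcription factors Atf4, Xbp1 and Ddit3. Ahsa2, a gene of the HSP90 activator family, was at 212 against 47.1 CPM, and Haus8, a subunit of the augmin complex of the mitotic spindle, at 139 against 29.5 CPM. The list's median was above 0 in each of the 3 smooth muscle-like clusters, at 1.76 in cluster 0, 2.09 in cluster 6 and 1.09 in cluster 13.

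On GRCm38, Hspa1b (ENSMUSG00000090877) lies on chromosome 17 from 34956436 to 34959238 and Hspa1a (ENSMUSG00000091971) beside it from 34969190 to 34972156, both on the minus strand. Hspb1 (ENSMUSG00000004951) lies on chromosome 5 from 135887919 to 135889563 on the plus strand. Hspa1a and Hspa1b are near-identical copies and Hspb1 has a processed copy, Hsp25-ps1 (88.0 against 10.2 CPM), so the split of reads within each group is uncertain. Free RNA may also carry Hspb1 into other droplets. In T cell-like cells it was at 315 CPM in the inhibitor and 54.3 CPM in the DMSO library, and its source there was not tested.

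**Figure D2:**
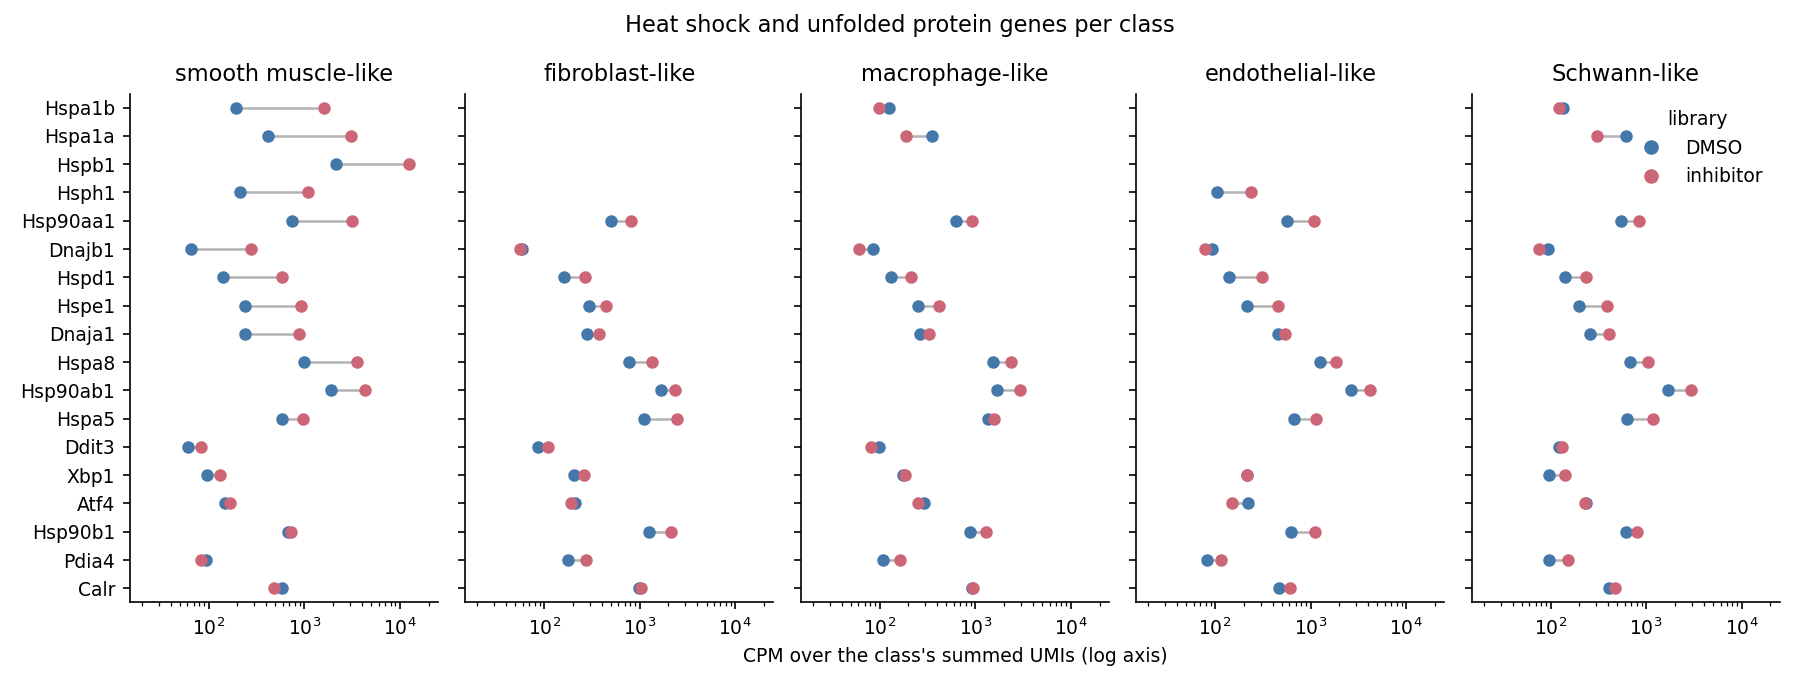
CPM (horizontal log axis) of the members of the heat shock and unfolded protein list in the 5 compared classes, 1 point per library, drawn where the gene was measured in the class. In smooth muscle-like cells Hspa1b, Hspa1a and Hspb1 lie farthest apart, with Hspb1 at 2141 and 12492 CPM; in macrophage-like and Schwann-like cells the inhibitor point of Hspa1a lies below the DMSO point, although in Schwann-like cells this order turned when cells called doublets were kept (log2 0.18).

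Genes of phenotypically modulated smooth muscle, which rise when contractile cells turn towards matrix production and inflammation, were lower in the inhibitor library. Spp1, encoding the matrix cytokine osteopontin, was at 77.7 against 1158 CPM (ratio 0.0671; 0.0645 to 0.0698), Lum, encoding the collagen-binding proteoglycan lumican, at 117 against 940 CPM. Timp1, an inhibitor of metalloproteinases, was at 183 against 673 CPM, and Vcam1, an adhesion molecule for leukocytes, at 163 against 539 CPM. Of 13 measured members, 9 were lower and 0 higher, with a median of -0.95 (-1.85 to -0.35; percentile 0). The contractile apparatus leaned the other way: Cnn1, encoding calponin, was at 2232 against 1355 CPM and Myh11 (ENSMUSG00000018830, chromosome 16, 14194535 to 14291372, minus strand), encoding smooth muscle myosin heavy chain, at 4600 against 3034 CPM. These 2 of 20 measured members were higher and 0 lower, with a median of 0.39 (0.27 to 0.45; percentile 100) that was 0.077 with cells called doublets kept. Acta2, encoding smooth muscle actin, was at 19781 against 14522 CPM, a ratio under 1.5.

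Matrix genes of smooth muscle-like cells were lower as well. In the list of collagens and matricellular proteins 9 of 20 members were lower and 0 higher (median -0.53; -0.98 to -0.27), among them Col1a1, a chain of type I collagen, at 1216 against 4122 CPM, Col8a1 at 57.0 against 221 CPM and Thbs1, encoding thrombospondin 1, at 188 against 525 CPM. In the elastic fibre list 8 of 15 were lower and 0 higher (median -0.62; -0.98 to 0.03). Eln (ENSMUSG00000029675, chromosome 5, 134702593 to 134747323, minus strand), encoding elastin, was at 2671 against 5722 CPM, Fbln2 at 51.6 against 231 CPM and Ltbp2, a microfibril protein, at 77.6 against 252 CPM. Of 8 matrix proteases 3 were lower, led by Mmp14, a membrane-bound collagenase, at 51.2 against 198 CPM, and 1 was higher, Adamts9, at 27.2 against 17.9 CPM. In the osteochondrogenic list 3 of 5 members were lower (median -0.90): Spp1, Comp, encoding a cartilage matrix protein, with a ratio of 0.469, and Acan, encoding aggrecan, at 26.5 against 53.9 CPM. The TGF-beta pathway list was divided, with 3 of 12 higher (among them the ligands Tgfb3, at 202 against 106 CPM, and Tgfb2, at 531 against 301 CPM) and 3 lower (Ltbp2, Bmp1 and Ccn1), and a median of 0.14 (-0.69 to 0.69). Cholesterol synthesis genes Fdps, Cyp51 and Sqle were the 3 of 6 members of their list that were higher (median 0.50; 0.31 to 0.71). Of 5 measured immediate early genes Atf3, at 205 against 103 CPM, and Jund, at 1165 against 748 CPM, were higher and Egr1, at 237 against 461 CPM, was lower (median 0.30).

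The cluster makeup of the class differed between the libraries: cluster 13, whose leading genes include Eln, Mgp, Spp1, Lum, Col1a1 and Ltbp2, held 34.4% of smooth muscle-like cells in the DMSO library (263 cells) and 5.38% in the inhibitor library (167 cells). The name of cluster 13 was close: its 10 leading genes held 2 smooth muscle and 2 fibroblast markers. Its marker score was 3.83 for smooth muscle and 2.94 for fibroblasts. Cluster 0, led by Tagln, Myh11 and Acta2, held 49.2% and 76.4%. Within cluster 0 the modulated list had a median of -0.72 (-1.12 to -0.06) and Vcam1 a log2 ratio of -1.43. The contractile median was 0.14 (-0.02 to 0.21), the collagen median -0.25 (-0.35 to -0.11) and the Eln log2 ratio -0.18. There Cnn1 (0.36), Myh11 (0.21), Ltbp2 (-0.45) and Fbn1 (-0.43) were under 1.5-fold, and the elastic fibre median was -0.21 (-0.43 to -0.04). In cluster 6 the modulated median was -0.74 (-1.22 to -0.28). In cluster 13 it was -0.03 (-0.84 to 0.27), and Vcam1 stood at 1631 CPM in the inhibitor and 1156 CPM in the DMSO library. The contractile median was 0.04 (-0.02 to 0.14) in cluster 6 and 0.30 (0.22 to 0.40) in cluster 13. The collagen median was -0.39 (-0.53 to -0.28) in cluster 6 and -0.32 (-0.68 to -0.08) in cluster 13. Cluster 13 carried most of the Spp1: it was at 879 against 2720 CPM there, but at 9.31 against 26.1 CPM in cluster 0 and 9.47 against 121 CPM in cluster 6.

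**Figure D3:**
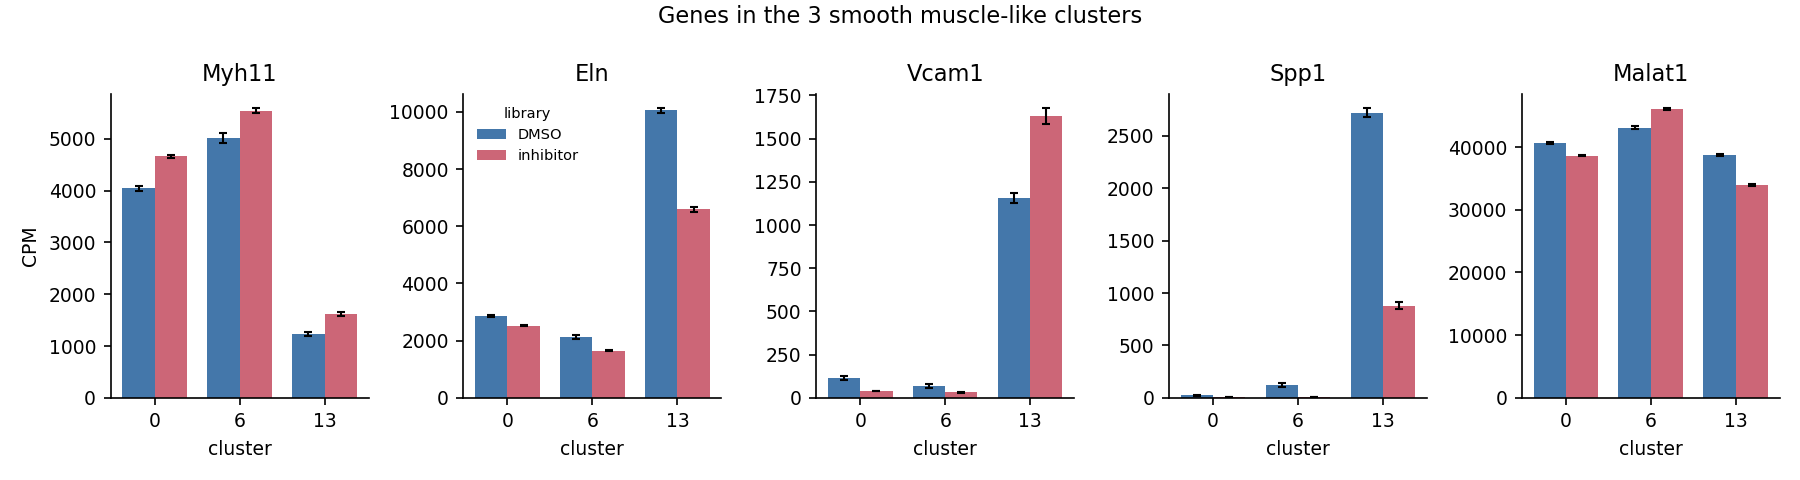
CPM (vertical axes) of 5 genes in smooth muscle-like clusters 0, 6 and 13 of the DMSO and the inhibitor library (bars), with exact 95% Poisson intervals that cover counting error only. Spp1 in cluster 13 stands at 2720 CPM in the DMSO and 879 CPM in the inhibitor library, while Vcam1 in the same cluster is higher in the inhibitor library.

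Malat1 (ENSMUSG00000092341, chromosome 19, 5795690 to 5802672, minus strand), a long non-coding RNA kept in the nucleus, was compared across the smooth muscle-like clusters as a gene picked before the data were examined. Over the class it was at 39756 CPM in the inhibitor and 40245 CPM in the DMSO library, a ratio of 0.988 (0.985 to 0.991). In cluster 0 it was at 38624 against 40625 CPM, in cluster 6 at 46082 against 43091 CPM, and in cluster 13 at 33942 against 38749 CPM. The median mitochondrial share of these cells, which with nuclear RNA can mark damaged cells, was 4.85 against 5.86% in cluster 0, 4.92 against 6.41% in cluster 6 and 3.60 against 4.53% in cluster 13. Neat1, another RNA kept in the nucleus, was lower in the inhibitor library in all 3 clusters, at 280.3 against 464 CPM, 222 against 369.9 CPM and 445 against 576 CPM. In the other 4 compared classes the log2 ratio of Malat1 lay between -0.13 in endothelial-like and -0.02 in macrophage-like cells.

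Fibroblast-like cells of the inhibitor library held less RNA of inflammatory genes. Cxcl13 (ENSMUSG00000023078, chromosome 5, 95956951 to 95961068, plus strand), a chemokine that attracts B cells, was at 63.0 against 419 CPM (ratio 0.150; 0.142 to 0.159), Cxcl1, which attracts neutrophils, at 64.8 against 267 CPM. The interferon-induced Cxcl9 and Cxcl10 were at 2.08 against 28.3 CPM and 15.8 against 59.1 CPM. Of 14 measured cytokines and chemokines, 10 were lower and 0 higher, with a median of -1.17 (-1.96 to -0.26; percentile 0). In the complement list 3 of 8 were lower and 0 higher: C3, the central component, at 2459 against 5296 CPM, C4b at 256 against 704 CPM and C1s1 at 469 against 758 CPM. C4b has a near-identical neighbour, so its level is uncertain. Among the 10 genes with the lowest ratios were also Lcn2, encoding the iron-carrier protein lipocalin 2, at 77.2 against 366 CPM, and Ptx3, a soluble pattern receptor, at 26.2 against 112 CPM. The others included Apod at 198 against 981 CPM, Chl1 at 72.2 against 345 CPM and Aldh1a2, a retinoic acid synthesis enzyme, at 16.4 against 94.8 CPM. Cxcl13 was also a leading gene of fibroblast-like cluster 2. Both Cxcl13 and Chl1 were leading genes of adipocyte-like cluster 11, with 471 DMSO and 39 inhibitor cells. What cluster makeup and free RNA add to the values of these 2 genes was not tested.

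Hspa5 led the measured members of the heat shock list in fibroblast-like cells, where 7 of 14 were higher and 0 lower (median 0.54; 0.07 to 0.76; percentile 100). Hsph1 had a larger ratio (175 against 67.7 CPM) but was left out by the minimum of 20% of the class where it was highest. Hspa5, encoding the endoplasmic reticulum chaperone BiP, was at 2476 against 1111 CPM, the cytosolic chaperone gene Hspa8 at 1356 against 777 CPM and Hsp90b1, of the endoplasmic reticulum, at 2116 against 1249 CPM. Creld2, a gene induced by endoplasmic reticulum stress, was at 241 against 52.9 CPM (ratio 4.56; 4.33 to 4.81). Rbp4, encoding a retinol carrier, was at 1219 against 156 CPM, Angptl7 at 198 against 35.5 CPM and Fmod, encoding the proteoglycan fibromodulin, at 305 against 76.2 CPM. Protease inhibitors were divided: Cst3, encoding cystatin C, was at 12538 against 3987 CPM, Timp3 at 1373 against 552 CPM and Reck 2.41-fold higher, while Timp1 and Serpina3n were lower. In the elastic fibre list 4 of 18 were higher, led by Fbln5 (610 against 244 CPM), and 5 were lower, led by Efemp1 (65.0 against 207 CPM). Of 20 collagens and matricellular proteins 6 were lower, among them Fn1, encoding fibronectin, at 1134 against 2253 CPM and Postn at 343 against 675 CPM, and the median was -0.34 (-0.57 to -0.04). The TGF-beta pathway genes Tgfbi (760 against 236 CPM) and Ccn2 (1135 against 385 CPM) were higher and Tgfbr2, Bmp1 and Ccn1 lower, with a list median of -0.02. Of 9 immediate early and dissociation-associated genes 5 were lower and 0 higher (median -0.61; -1.19 to -0.26).

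Different clusters held most fibroblast-like cells: clusters 2 and 7 held 39.3 and 28.2% of them in the DMSO library but 18.7 and 5.07% in the inhibitor library. There clusters 3 and 4 held 35.9 and 37.4% against 18.8 and 7.89%. Within cluster 3 the log2 ratio was 2.42 for Creld2, 1.49 for Hspa5, 1.28 for Rbp4, -1.58 for Cxcl1, -0.72 for C3 and 0.38 for Cst3. It turned for Angptl7 (-0.999), Fmod (-0.39), Timp3 (-0.11) and Timp1 (0.43), and Fbln5 (0.23), Reck (0.15), C1s1 (-0.34) and Bmp1 (-0.043) were under 1.5-fold. The collagen median was -0.41 (-0.60 to -0.24) in cluster 2, but in cluster 3 it was 0.02 (-0.36 to 0.09) and the cytokine median -0.22 (-1.03 to 0.49). The cytokine median was -0.77 (-1.78 to -0.12) in cluster 2 and -0.66 (-1.55 to -0.17) in cluster 4, but 0.05 (-1.11 to 0.47) in cluster 7.

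Macrophage-like cells of the inhibitor library carried more RNA of genes known from resident tissue macrophages. Cd163 (ENSMUSG00000008845, chromosome 6, 124304656 to 124330527, plus strand), the scavenger receptor for haemoglobin, was at 313 against 70.7 CPM (ratio 4.43; 4.07 to 4.82). Pf4, a chemokine, was at 849 against 386 CPM, Cbr2, a carbonyl reductase, at 231 against 114 CPM, and Folr2, a folate receptor, at 187 against 94.3 CPM. Of 10 measured members of the resident-like list 7 were higher and 0 lower, with a median of 0.86 (0.26 to 1.13; percentile 100). Mgl2, a lectin of alternatively activated macrophages, was at 348 against 103 CPM, Ccl12, a monocyte chemoattractant, at 434 against 195 CPM, and Fkbp5, a glucocorticoid-induced co-chaperone gene, at 164 against 73.8 CPM. Cd5l, an apoptosis inhibitor of macrophages, was at 59.5 against 315 CPM. Cxcl9 rested on 1 UMI in the inhibitor library, with a ratio of 0.00608 (0.000154 to 0.0341) to 37.3 CPM in the DMSO library.

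In the list of lipid-handling macrophages, named for the lipid receptor Trem2, 2 of 11 members were lower and 0 higher (median -0.48; -0.59 to -0.14): Abca1, a cholesterol exporter, at 394 against 637 CPM, and Lipa, the lysosomal acid lipase, at 235 against 358 CPM. Trem2 itself was at 552 against 554 CPM. Of 20 immediate early genes, 13 were lower and 0 higher (median -0.72; -0.84 to -0.46), with Dusp1, a MAP kinase phosphatase, at 446 against 935 CPM and Fosb at 198 against 445 CPM. The lysosomal protease genes Ctsl (839 against 1682 CPM) and Ctsd (2386 against 3696 CPM) were lower, with 3 of 11 matrix proteases lower and 0 higher. In the interferon response list 4 of 18 were lower and 0 higher (median -0.18), among them Ifit2 and Rsad2. However, the median log2 ratio of interferon response in macrophage-like cells was 0.0037 when each library was clustered alone. In the cell cycle list 5 of 19 were higher and 0 lower (median 0.26), among them the replication genes Mcm6 and Tyms, but the median was -1.22 under that setting. Heat shock genes were divided, with Hsp90ab1 (2910 against 1694 CPM) among 5 of 16 higher and Hspa1a (187 against 355 CPM) lower. Apoe, the gene whose deletion defines the strain, was at 923 against 1101 CPM, and a 3' tag cannot check that deletion.

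Most macrophage-like cells of both libraries lay in cluster 1, which held 83.1% of them in the inhibitor and 66.9% in the DMSO library. Cluster 9, led by Spp1, Gpnmb, Fabp5 and Cd5l, held 12.2 and 29.7%. The resident-like list had a median of 0.83 (0.30 to 1.55) within cluster 1 but -1.26 (-1.75 to -0.77) within the 77 inhibitor and 472 DMSO cells of cluster 9. The lipid-handling list had a median of -0.42 (-1.21 to 0.18) within cluster 1, where Lipa (-0.21), Ctsl (-0.32) and Ctsd (-0.52) were under 1.5-fold, and of 0.29 (-0.34 to 0.40) within cluster 9.

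In endothelial-like cells the activation genes were divided between the libraries. Ackr1 (ENSMUSG00000037872, chromosome 1, 173331886 to 173333750, minus strand), an atypical chemokine receptor of venules, was at 12.8 against 90.5 CPM (ratio 0.141; 0.0997 to 0.194), and Lrg1 at 233 against 512 CPM. The selectins Selp and Sele, which capture leukocytes, were at 192 against 309 CPM and 27.4 against 44.3 CPM. Nos3, the endothelial nitric oxide synthase, was higher at 253 against 141 CPM, as was the adhesion molecule Vcam1 at 714 against 418 CPM. In all, 2 of 15 members of the activation list were higher and 4 lower, with a median of -0.18 (-0.60 to 0.25). The activation median was -0.40 (-0.56 to -0.12) within cluster 8 and -0.11 (-0.57 to 0.31) within cluster 12. Among the highest ratios were Apln, encoding the peptide apelin, at 50.4 against 6.16 CPM (8.18; 5.79 to 11.8), Gkn3 at 348 against 85.5 CPM and Cytl1 at 2440 against 720 CPM. Eln was at 2069 against 1084 CPM. Of 6 matrix proteases 5 were lower and 0 higher (median -0.80; -1.33 to -0.35), with Mmp14 at 52.6 against 140 CPM. Basement membrane collagens Col15a1 (97.6 against 260 CPM), Col4a1 and Col4a2 were lower. Heat shock genes were higher for 7 of 14 members (median 0.61; 0.03 to 1.06), with Hsph1 at 240 against 106 CPM, and immediate early genes lower for 7 of 11 (median -0.72; -1.01 to -0.25), with Egr1 at 280 against 568 CPM. The immediate early median was -0.77 (-1.24 to -0.40) within cluster 8 but -0.20 (-0.67 to -0.11) within cluster 12. Cluster 8, led by the capillary genes Cd36 and Gpihbp1, held 36.1% of endothelial-like cells in the inhibitor and 50.9% in the DMSO library, and cluster 12, led by Cytl1, Pecam1 and Vwf, 49.2% and 25.5%. Within cluster 12 the log2 ratio was -2.60 for Ackr1, 1.15 for Cytl1, 1.39 for Gkn3, 0.45 for Eln and 0.31 for Vcam1.

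As in fibroblast-like, macrophage-like and endothelial-like cells, the immediate early and dissociation-associated list was lower in Schwann-like cells of the inhibitor library. Fosb, an AP-1 transcription factor subunit, was at 601 against 1195 CPM (ratio 0.503; 0.462 to 0.547), Klf6 at 551 against 1046 CPM and Zfp36, which destabilises cytokine mRNAs, at 268 against 528 CPM. Of 17 measured members 10 were lower and 0 higher, with a median of -0.62 (-0.89 to -0.44; percentile 0). Chaperone genes were higher for 8 of 16 members and lower for 1 (median 0.56; -0.04 to 0.71), with Hspa5 at 1167 against 635 CPM, Hsp90ab1 at 2979 against 1697 CPM and Hspe1, the partner of the mitochondrial chaperonin, at 390 against 198 CPM. The endoplasmic reticulum stress genes Sdf2l1 (89.9 against 26.0 CPM) and Creld2 (57.8 against 19.1 CPM) and the potassium channel gene Kcnk1 (124 against 34.1 CPM) had some of the highest ratios. The chemokine Ccl2 (18.4 against 69.3 CPM), the inflammatory caspase gene Casp4 (18.4 against 70.5 CPM) and Angptl4 (70.6 against 217 CPM) had some of the lowest. The lowest log2 ratio (-1.83, after adding 5 CPM) was that of CT010467.1, a gene annotated as ribosomal RNA, at 206 against 748 CPM. Of 12 mitochondrially encoded genes 2 were higher, among them mt-Co3 (log2 0.79), and 1 was lower, mt-Nd6, at 82.6 against 157 CPM. Hspa1a was at 307 against 612 CPM, a direction that turned with doublets kept (log2 0.18). This class rests on 227 cells of the inhibitor and 464 of the DMSO library, and cluster 16 held 37.4% and 48.7% of them. The immediate early median was -0.78 within cluster 16, -0.62 (-0.84 to -0.30) within cluster 20 and -0.81 (-1.08 to -0.55) within cluster 23. Within cluster 16 the log2 ratio was 1.42 for Creld2, 0.88 for Hspa5, 0.79 for mt-Co3 and -0.23 for mt-Nd6.

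**Figure D4:**
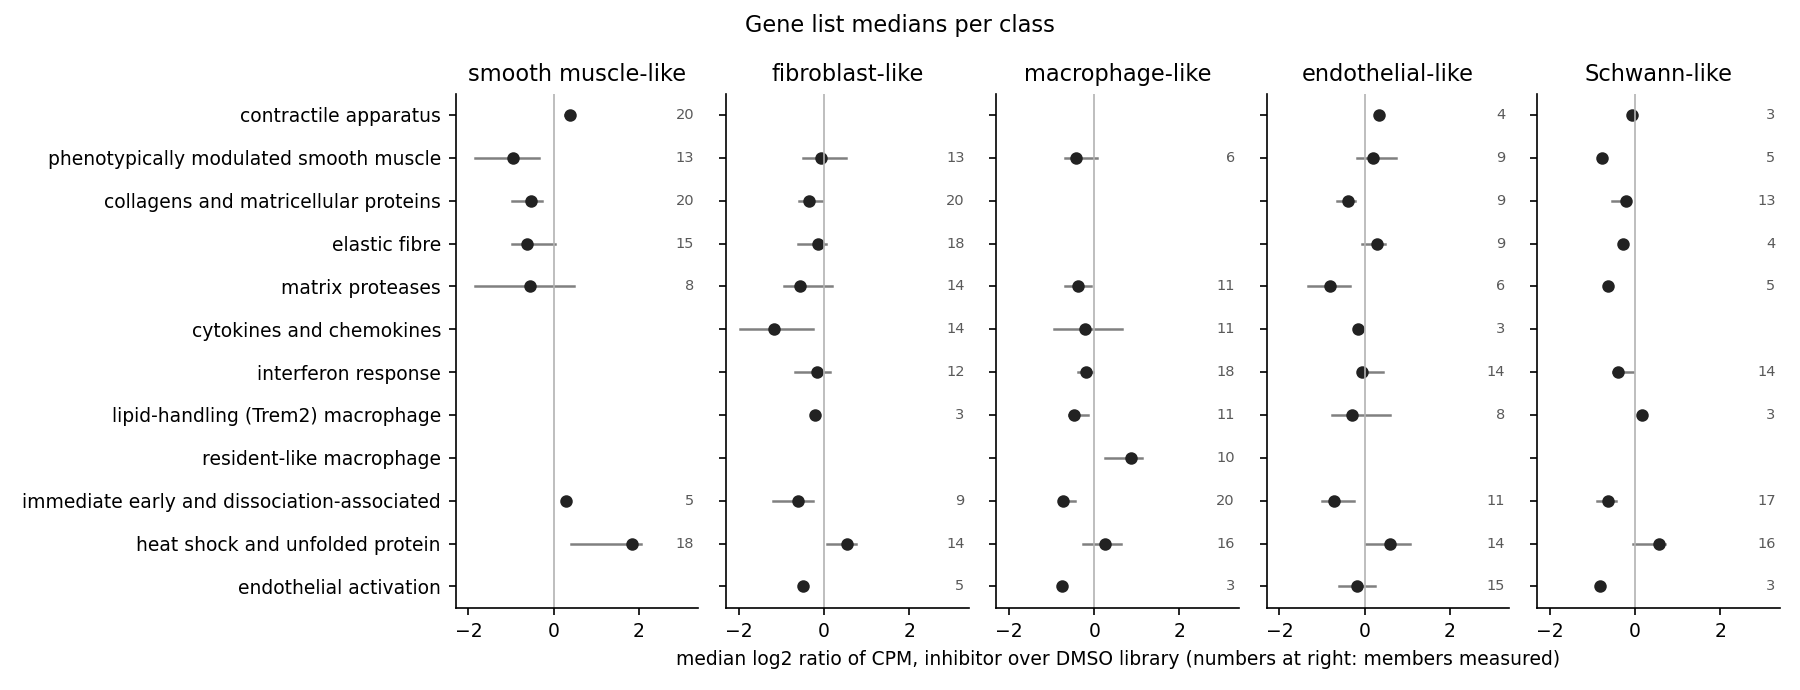
Median log2 ratio of CPM, inhibitor over DMSO library (horizontal axes), for 12 gene lists in the 5 compared classes (points), with order-statistic intervals over the members (lines, drawn from 6 members on) and the number of members measured at the right. In smooth muscle-like cells the heat shock list lies at 1.85 and the modulated list at -0.95, in fibroblast-like cells the cytokine list at -1.17 and in macrophage-like cells the resident-like list at 0.86.

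Across whole libraries, mitochondrial UMIs were 3.82% of all in the inhibitor and 4.29% in the DMSO library, ribosomal protein UMIs 10.5 and 11.6%, and haemoglobin UMIs 0.00683 and 0.0153%. Both libraries carried Y-linked Ddx3y (90.2 and 95.6 CPM) and almost no Xist (0.216 and 0.166 CPM), the levels of male tissue. Free RNA differed with the cell mix: the macrophage gene C1qa had a UMI in 8.26% of fibroblast-like cells in the inhibitor library and 39.3% in the DMSO library (medians of 8932 and 15695 UMIs), while Acta2 had a UMI in 83.3 and 59.5% of macrophage-like cells (medians of 5657 and 6888 UMIs). Genes under 20% of their level in the class where they were highest were therefore not measured in the lower class.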

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

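All tests of explanations in this part were chosen after the results were seen. Vcam1, an adhesion molecule for leukocytes, was higher in endothelial-like cells of the inhibitor library (log2 0.76) and lower in smooth muscle-like cells (-1.69), a gap of 2.46. Elastin (Eln; 0.93 and -1.10, gap 2.03), thrombospondin 1 (Thbs1; 0.74 and -1.46, gap 2.19), the angiotensin-converting enzyme gene Ace (0.58 and -0.82, gap 1.41) and the growth factor Gas6 (0.63 and -0.60, gap 1.23) were split the same way between these 2 classes. The protease gene Adamts9 was split the other way, higher in smooth muscle-like (0.49) and lower in endothelial-like cells (-0.91), a gap of 1.40. The complement gene C4b was higher in macrophage-like (0.86) and lower in fibroblast-like cells (-1.44), a gap of 2.30. The HSP70 gene Hspa1a was higher in smooth muscle-like (2.85) and lower in Schwann-like cells (-0.98), a gap of 3.83, although its Schwann-like value was 0.18 with doublets kept. Within 1 cluster per class several of these values were under 1.5-fold: in endothelial-like cluster 12 Eln (0.45), Vcam1 (0.31), Thbs1 (0.28) and Ace (0.27), and in smooth muscle-like cluster 0 Eln (-0.18), Gas6 (-0.28) and Adamts9 (0.36). In smooth muscle-like cluster 13 Vcam1 was higher in the inhibitor library (1631 against 1156 CPM), while Eln was lower there (6591 against 10048 CPM) and in cluster 6 (1651 against 2127 CPM). These 8 genes stand here because 2 classes differ in opposite directions; the difference between classes was not tested, and each class is 1 library per group.

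RNA of brown fat appeared in cells that the comparison of classes leaves unnamed. An unnamed cluster of 73 DMSO cells (0.863% of the library), with a median of 696 UMIs, was led by Ucp1, the uncoupling protein of brown adipocytes, at 5488 CPM and in 97.3% of its cells. The inhibitor library held 0 cells of this cluster, which allows up to 3 cells or 0.0403%. Ucp1 itself was still found in 0.537% of its cells (671 UMIs), against 6.62% of DMSO cells (6636 UMIs). Membership of the cluster is therefore no measure of all cells with Ucp1. Among the adipocyte-like cells, cluster 28, with Scd1, Ucp1 and Cidea among its leading genes, held 64 DMSO and 0 inhibitor cells. The unnamed cluster stands here because it lies above what a count of 0 allows.

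Heat shock genes were higher in smooth muscle-like cells and, for part of the list, in the 4 other compared classes of the inhibitor library. Free RNA from smooth muscle cells was weighed as the source outside that class. The minimum of 20% of the class where a gene was highest, which the counts above use, was left out. Of 36 values higher there, the increase exceeded what such RNA could bring by the highest of 4 marker ratios for 86.1% (31). This argues against such RNA as the source of these 31. Values above the 20% minimum nearly had to pass by their level alone, so the 86.1% is no measure of strength. Under that minimum, Hsph1 in Schwann-like, fibroblast-like and macrophage-like cells and Hspb1 in endothelial-like cells passed. The 5 values that did not pass stay open to free RNA: Hspb1 in Schwann-like, fibroblast-like and macrophage-like cells and Hspa1b in endothelial-like and fibroblast-like cells. A general dissociation response was judged by the immediate early list. The highest of its 4 medians outside smooth muscle-like cells was -0.61, which argues against a response that raises those genes there. In smooth muscle-like cells the median was 0.30, so such a response stays open in that class. A response that raises heat shock genes without immediate early genes could not be seen by this list and stays open in every class. Handling of 1 library rather than the inhibitor cannot be told apart from an effect of the inhibitor with 1 library per group, and both stay open and untested.

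Smooth muscle-like cells were a larger share of the inhibitor library. Dilution by adipocyte-like cells could explain little of it, since the log2 share ratio was 2.07 without them, and the lowest value over 13 alternatives of clustering, naming and filtering was 1.97. The yield of smooth muscle cells from the tissue taken cannot be told apart from a difference in the wall: their share among smooth muscle-like and fibroblast-like cells was 61.1% in the inhibitor library, which both would give. Whether the inhibitor altered the wall stays open and untested.

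Genes of modulated smooth muscle were lower in smooth muscle-like cells of the inhibitor library. Free RNA from macrophages and fibroblasts was weighed without that minimum, which adds Cd34, Dcn, Lgals3 and Ly6a to the 9 lower members counted above. Such RNA could cover the difference for 53.8% of these 13 members (7) by the highest marker ratio and for 0 of 13 by the lowest, so it stays open, although 6 members, among them Spp1, Vcam1 and Mgp, differed by more than either bound. Members of the list set neither ratio, but the highest is that of Col1a1, a leading gene of smooth muscle-like cluster 13 and so no clean measure of free RNA. In cluster 6 the list median was -0.74 (-1.22 to -0.28). It was -0.72 (-1.12 to -0.06) in cluster 0 and -0.0298 (-0.84 to 0.27) in cluster 13. Members were those measured over the whole class, with no minimum within a cluster, so free RNA may enter these medians. In clusters 0 and 6, 0 of 13 members were above 0, which argues against the mix of these clusters as the whole cause. In cluster 13 the interval held 0, and a finer mix within clusters was not tested. The mix therefore stays open as a part of the cause. An effect of the inhibitor stays open and untested.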

How the results depend on the processing

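The 17 alternatives were set before the data were examined; leaving out adipocyte-like cells, using 1 cluster per class and the 3 earlier naming rules were added after results were seen. No paired analysis was possible because each group holds 1 library, and for the same reason no library could be left out. Over all alternatives, 5597 gene values kept their call by size or, uncalled, moved by under 1.5-fold, 275 did not, and 19 called ones changed sign. List medians stayed within their interval (within 0.3 where they had none) 1888 times, left it 85 times and changed sign 9 times; share ratios did so 134, 21 and 1 times. The log2 share ratio of smooth muscle-like cells ranged from 1.97 to 2.70 over 13 alternatives. Over 21 alternatives the heat shock median in smooth muscle-like cells ranged from 1.76 to 1.94, the modulated median from -1.40 to -0.60, the cytokine median in fibroblast-like cells from -1.47 to -0.35 and the resident-like median in macrophage-like cells from 0.71 to 1.12. Thinning to 2000 UMIs left out 1351 DMSO and 884 inhibitor cells. The causes of the shifts below were not tested.

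With at most 10% mitochondrial UMIs, the log2 share ratio was -0.66 for endothelial-like and 0.031 for fibroblast-like cells. With no mitochondrial maximum it was 2.54 for smooth muscle-like cells, and their contractile median was 0.076. With at least 1000 genes per cell, share ratios were -0.66 (endothelial-like), -0.0054 (fibroblast-like, sign changed) and 2.06 (smooth muscle-like), and the MHC class II median in macrophage-like cells was 0.047 (sign changed). With doublets kept, the smooth muscle-like share ratio was 2.69, the Trem2 list median in macrophage-like cells -0.65 and the contractile median 0.077, and Hspa1a in Schwann-like (0.18) and Eln in fibroblast-like cells (-0.0065) changed sign. With all variable genes, share ratios were 0.0158 (fibroblast-like) and -0.96 (macrophage-like). With 15 components, the smooth muscle-like share ratio was 2.70, the contractile median 0.11 and the log2 ratio of Top2a in endothelial-like cells 0.0281 (sign changed). With each library clustered alone, share ratios were -0.81 (endothelial-like) and -0.88 (macrophage-like) and the contractile median 0.22; the median log2 ratio of interferon response in macrophage-like cells (0.0037) changed sign there, as did their MHC class II (0.038) and cell cycle (-1.22) medians and the genes Mcm5 (-0.062) and Ifitm6 (0.77), and Eln in fibroblast-like cells (-0.16). With the mean of each cell's CPM, the cell cycle median in fibroblast-like cells was -0.18 (sign changed) and the Trem2 list median -0.59. After thinning, the histone deacetylase median in endothelial-like cells was 0.068 (sign changed) and the Trem2 list median -0.61.

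Without adipocyte-like cells, share ratios were 0.016 (fibroblast-like) and 2.07 (smooth muscle-like). Under the third naming rule the smooth muscle-like share ratio was 1.97. Within 1 cluster per class, with members measured anew there, the contractile median was 0.14, and signs changed for the interferon median in Schwann-like cells (0.0152), the collagen (0.0362) and glycolysis (0.037) medians in fibroblast-like cells, Idi1 in Schwann-like (-0.46), Mki67 (0.78) and Top2a (0.50) in endothelial-like, and in fibroblast-like cells Tnfrsf11b (-0.49), Timp1 (0.43), Mfap4 (-0.089), Fbn1 (0.29), Loxl2 (0.42), Timp3 (-0.11), Ifit3 (-0.31), Bmp4 (-0.30), Angptl7 (-0.999) and Fmod (-0.39).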

Other observations

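No explanation was tested in this part. Transcripts of adipose tissue were more abundant in the DMSO library as a whole: Adipoq, encoding the fat hormone adiponectin, was at 324 CPM there and 37.8 CPM in the inhibitor library, and Ucp1 at 68.7 and 9.07 CPM. Haemoglobin RNA was low in both, with Hbb-bs at 90.1 and 41.9 CPM. Of genes outside the comparisons above, the chemokine gene Cx3cl1 (46.2 and 9.99 CPM) and the Wnt antagonist gene Frzb (136 and 27.1 CPM) were lower in smooth muscle-like cells of the inhibitor library. Tnfaip3, a brake on NF-kappa-B signalling, was at 136 CPM in DMSO and 50.2 CPM in inhibitor macrophage-like cells. In endothelial-like cells the early response gene Apold1 was at 251 and 62.8 CPM.

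In smooth muscle-like cells, of 13 measured histone deacetylases and chromatin remodellers 0 were higher or lower (median -0.08; -0.13 to 0.08), and of 13 glycolysis and hypoxia genes 0, although the median of the latter was -0.22 (-0.41 to -0.09) at percentile 0.38 of the matched random lists. Of 6 renin-angiotensin and oxidant genes 1 was lower, Ace, at 49.9 against 92.2 CPM. In macrophage-like cells 0 of 7 MHC class II genes were higher or lower (median -0.11; -0.16 to -0.01). The median log2 ratio of all measured genes lay between -0.03 in smooth muscle-like and 0.05 in Schwann-like cells.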
